A study of Homo sapiens with 6 samples.

How the data were processed

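RNA was sequenced from MCF7 cells 72 h after transfection of an siRNA against EP300 (sip300) or a non-targeting siRNA (siNT), in 3 libraries per group, with groups and replicate numbers taken from the labels. Per the labels' protocols, libraries were made with a TruSeq RNA v2 kit, which does not mark strand, and read in pairs of 43 and of 80 bp on an Illumina NextSeq instrument. The labels give both lengths for each library and do not divide the counts by run. The submitters' processing notes name bcl2fastq 2.17.1.14, cutadapt 1.12, TopHat2 2.0.14, HTSeq 0.6.0 and DESeq2 1.12.4 as the authors' tools and GRCh38 as the genome build.

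The authors' deposited gene table gives whole-number read counts per gene and library, not normalized, and the authors' own log2 fold change, p-value and adjusted p-value for sip300 against siNT. Of 60675 genes 50026 hold counts and 10649 hold a question mark in place of a value, 4198 of them microRNA genes and 0 protein-coding genes, and the latter 10649 genes were left out. The authors also deposited 5 rMATS tables, 1 per event type, with a p-value, a false discovery rate, an inclusion level difference as a fraction and a pair of significance columns (JnR_Sig and JO_Sig) per event. The rMATS version and the rule of those columns are not given in the sources used here. Of the columns in each such table, 6 hold values per library under names that cannot be tied to siNT or sip300, and these 30 columns were not used. Splicing is therefore reported from the authors' values alone, without a direction, and no test of splicing was computed here.

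The test differed from the plan made before the data were examined. A quasi-likelihood count model had been planned and was not run, nor was a second count model that had been listed beside it, because the question marks kept the columns from being recorded as pure counts. The genes that were kept hold whole-number counts, so the values themselves did not forbid these models. limma-voom, which had been listed as a second choice, replaced the quasi-likelihood model after the format of the table was seen. For a table without counts the plan had named limma on log2(value + 1). That test, on CPM, was added as an alternative only after the data were seen. Genes with at least 10 counts in a library of median size in at least 3 libraries and a total of at least 15 were kept, which left 19166. Libraries were scaled by trimmed means of M-values (TMM) computed here, with trims of 0.3 and 0.05, giving factors of 0.993, 0.952 and 0.998 for siNT replicates 1 to 3 and 1.02, 1.03 and 1.01 for sip300. Genes were called at an adjusted p under 0.05 by limma-voom (limma 3.58.1, R 4.3.3) with Benjamini-Hochberg adjustment over all tested genes. The 28 gene lists, the design, the other settings to be tried and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated, with adjustment over the 28 lists, and members were also counted when adjusted over the list alone.

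Genes named by the rule were EP300 and CREBBP, then the 8 largest rises and 8 largest falls among called genes with a symbol, a mean of at least 5 CPM and groups that did not overlap. From each list that passed its test or had at least 1 in 3 of its tested members changed up to 4 members with the smallest adjusted p were named, and from other lists up to 2. For splicing the rule took the 5 largest differences each way for skipped exons and 3 each way for other types. Its conditions on coverage and on non-overlapping libraries could not be applied, so these events were taken from those that the first significance column marks.

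Whether equal replicate numbers pair the libraries was examined before the calls of the fits were compared. Deviations from the group means correlated at 0.308, 0.589 and 0.388 across genes for replicates 1, 2 and 3, all above the limit of 0.1 set for pairing, and between -0.424 and 0.122 for unequal numbers. Among the latter, siNT replicate 1 with sip300 replicate 3 (0.122) and siNT replicate 3 with sip300 replicate 1 (0.106) also exceeded the limit. The limit alone therefore does not establish pairing. The numbers come from the labels, which do not say what they share. The fit without the block remains the main one, as planned, and blocked values stand beside results that they change. Pairs of libraries within a group differed by 10.5 to 59.3 chi-square units per degree of freedom, so none was a copy of another.

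Alternatives were median-of-ratios factors, library totals only, no filter beyond a total above 0, a mean of at least 1 CPM, pseudocounts of 0.1 and 1 on log2 CPM, GC content and length offsets (lowess span 0.3), the replicate block with and without them, a minimum of 2-fold and each library left out. Gene positions were compared with GENCODE 29, where 19574 of 19592 protein-coding genes (99.91%) lay at the same place, and GC content was known for 99.2% of tested genes. Differences of medians were tested with 100000 permutations and shares with two-sided Fisher's exact tests, and intervals are at 95%. The floor of 3 counts covers counting error only, as the reads carry no molecular identifiers. The intervals of odds ratios and shares treat genes or exons as independent and do not measure the spread between libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

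The steps were tested on simulated data. For sip300 against siNT, over 18905 genes in 3 runs with 200 changed genes each, 88.6% of genes changed 1.5-fold, 99.0% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 4.64% of calls were false. All 4 shifted lists and 0 null lists were called. The simulated genes were drawn independently, with a common dispersion and without effects of replicate number. Changed genes and list members were taken only from genes of higher mean count. The dispersion of 0.00585 was a median over such genes. These runs therefore cannot show the recovery of genes with low counts or a larger spread. Nor can they show the false-call share or the error of the list test where genes are correlated, as in the real libraries. The test of exon length called 2 of 60 null sets and 20 of 20 shifted sets.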

Results

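Gene expression and alternative splicing were measured by RNA sequencing in MCF7 cells, an oestrogen receptor-positive luminal breast cancer line. The cells had been transfected for 72 h with a small interfering RNA (siRNA) against EP300 (sip300, 3 libraries) or with a non-targeting siRNA (siNT, 3 libraries). EP300 encodes p300, a lysine acetyltransferase that serves as a co-activator of transcription, and the study was set up to follow expression and splicing after its loss. Gene counts summed to 66894351, 74929231 and 57948365 in siNT replicates 1 to 3 and to 63765896, 79698018 and 64938653 in sip300 replicates 1 to 3. At these depths 3 counts correspond to between 0.0376 and 0.0518 CPM, the counts of a gene scaled to library size. Expression levels are given as mean ± SD in scaled CPM over 3 libraries per group, and fold changes as sip300 minus siNT on the log2 scale with the standard error of the limma-voom fit. The first principal component held 48.8% of the variance and separated the groups, and the second held 27.2% and set both libraries numbered 2 apart from the others. Mitochondrially encoded transcripts took 4.51 to 4.59% of the counts in the siNT libraries and 4.08 to 4.40% in the sip300 libraries. The labels do not say whether libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

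The targeted gene was lower in each sip300 library. EP300 (ENSG00000100393, GRCh38 chromosome 22, 41091786 to 41180079) stood at 97.0, 96.8 and 93.6 CPM in siNT replicates 1 to 3 and at 35.1, 28.6 and 41.2 CPM in sip300 replicates 1 to 3. The group means were 95.8 ± 1.93 and 35.0 ± 6.29 CPM (SD, n = 3), a 2.78-fold fall (log2 fold change -1.48 ± 0.12 SE, limma-voom, Benjamini-Hochberg adjusted p = 0.00146). The antisense gene EP300-AS1 overlaps this locus and the library kit does not keep strand, so a part of these reads could not be assigned to a strand. CREBBP, the paralogue that encodes CBP (chromosome 16, 3725054 to 3880726), was at 152 ± 8.78 CPM in siNT and 157 ± 10.1 CPM in sip300 and passed no test (log2 fold change 0.04 ± 0.08 SE, limma-voom adjusted p = 0.783).

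Of the 16 genes named by the size of their change, 8 were higher and 8 lower in sip300. CYP24A1, the enzyme that starts the breakdown of active vitamin D, rose 5.16-fold from 4.53 ± 1.59 to 23.1 ± 6.93 CPM (chromosome 20, 54153449 to 54173973; log2 fold change 2.37 ± 0.29 SE, limma-voom adjusted p = 0.00438). CYP26B1, which degrades retinoic acid, rose 2.68-fold from 3.27 ± 0.520 to 8.70 ± 0.798 CPM. The antiviral gene RSAD2 rose 4.38-fold and its neighbour CMPK2 3.83-fold, although these genes overlap on chromosome 2 (6865806 to 6898239 and 6840570 to 6866635) and their reads cannot be fully parted. MAP1B, a microtubule-associated protein, rose 4.13-fold, PLEKHH2 3.46-fold and the interferon-induced IFIT3 2.91-fold (limma-voom adjusted p = 0.0499), and the homeobox factor HHEX rose from 3.09 ± 0.334 to 9.43 ± 3.14 CPM. Among the falls, FAM65C dropped 8.48-fold from 19.5 ± 0.143 to 2.39 ± 0.669 CPM (chromosome 20, 50586108 to 50691528; log2 fold change -3.08 ± 0.18 SE, limma-voom adjusted p = 0.000671). S100A9, a calcium-binding subunit of calprotectin, fell 6.57-fold, the sphingosine-1-phosphate transporter SPNS2 6.35-fold, the protease CAPN8 6.18-fold and the short-chain dehydrogenase DHRS2 6.12-fold, the last from 264 ± 65.9 to 43.7 ± 13.6 CPM. AMBP, the precursor of alpha-1-microglobulin and bikunin, fell 5.74-fold, the gel-forming mucin MUC5B 5.72-fold and SUSD2 5.33-fold, with limma-voom adjusted p-values of 0.00116, 0.00577 and 0.000647. The naming rule required the 3 sip300 libraries to lie apart from the 3 siNT libraries in each of these 16 genes. The separation in the plot of expression per library follows from that rule and is no further evidence. IFIT3, PLEKHH2 and SPNS2 overlap the tested genes LIPA, C1GALT1C1L and MYBBP1A, so their reads are uncertain to that extent. The calls of 6 of them were lost when single libraries were left out. Without siNT replicate 1 the limma-voom adjusted p rose to 0.0517 for HHEX, 0.0778 for CMPK2, 0.0590 for PLEKHH2, 0.172 for IFIT3 and 0.0614 for S100A9. Without sip300 replicate 1 it rose to 0.0536 for MAP1B, 0.0509 for CMPK2, 0.103 for PLEKHH2 and 0.0995 for IFIT3, and without sip300 replicate 3 to 0.0780 for PLEKHH2, 0.105 for IFIT3 and 0.0502 for S100A9. S100A9 also lost its call without siNT replicate 3 (0.0515). IFIT3 lost it without siNT replicate 2 (0.0849) and sip300 replicate 2 (0.0735) as well, and without both libraries numbered 2 (0.0738). It also lost it with median-of-ratios factors (0.0510), a mean of at least 1 CPM (0.0523), pseudocounts of 0.1 (0.0531) and 1 (0.0541), and GC content and length offsets (0.0537).

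**Figure D1:**
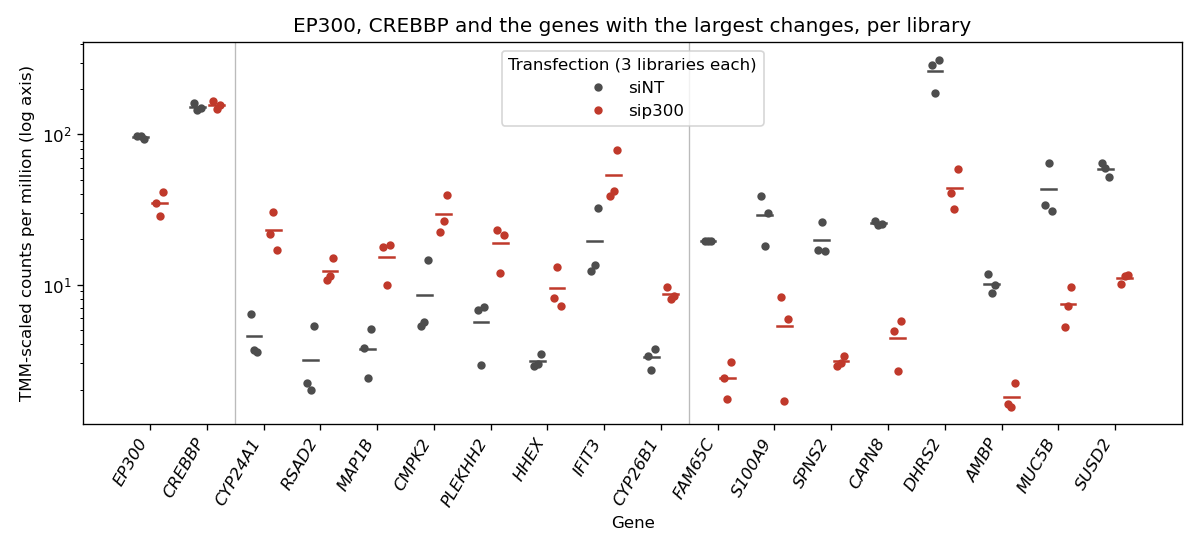
Scaled CPM (counts scaled to library size) on a log axis for EP300, its paralogue CREBBP and the 8 genes with the largest rises and 8 with the largest falls among those past the threshold. Each point is 1 of the 3 siNT or 3 sip300 libraries and each line is the group mean; EP300 lies at 93.6 to 97.0 CPM in siNT and 28.6 to 41.2 CPM in sip300, and CREBBP overlaps between the groups.

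Across the transcriptome 1684 of 19166 tested genes passed the threshold, of which 651 were higher and 1033 lower in sip300 (limma-voom with Benjamini-Hochberg adjustment), and 626 of them changed at least 2-fold (167 higher and 459 lower). The 3 libraries of each group did not overlap in 30.3% of tested genes, where chance gives 10% for independent libraries, a value that leaves out the pairing by replicate number. With the replicate number as a block 6238 genes passed, 3222 higher and 3016 lower, and all 1684 genes were among them. The share of higher genes was 38.7% in the fit without the block, 51.7% with it and 53.2% when libraries were scaled by their totals alone (1028 higher and 905 lower). With 1 library left out the share was lower, at 21.9 to 33.8%. The count fell to 653 without siNT replicate 1 (143 higher and 510 lower), 944 without siNT replicate 3 (319 and 625) and 518 without sip300 replicate 1 (141 and 377). It was 845 without sip300 replicate 2 (285 and 560) and 1253 without sip300 replicate 3 (406 and 847), and 453 genes passed in each of the 6 fits that leave out 1 library. The authors' deposited table marks 5194 genes at an adjusted p below 0.05, 2633 higher and 2561 lower, and 1627 of the 1684 genes are among them with the same sign in all 1627.

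The oestrogen-response and luminal genes that passed the test fell. Of 35 tested members of the oestrogen-response list 13 fell and 0 rose (21 and 1 adjusted over the list alone, 27 and 2 with the replicate block). CTSD, the lysosomal protease cathepsin D (chromosome 11, 1752752 to 1763992), fell from 551 ± 32.3 to 228 ± 5.31 CPM (log2 fold change -1.27 ± 0.07 SE, limma-voom adjusted p = 0.000647). The protease inhibitor SERPINA1 fell by 2.21, the secreted glycoprotein STC2 by 0.86 and the prolactin receptor PRLR by 1.61 on the log2 scale. At the preset correlation the list as a whole was lower than other genes (camera, adjusted p = 3.14e-10). It did not pass with an estimated correlation (camera, adjusted p = 0.629), and no other list did. With the replicate block some called lists failed in this way although their estimate lay below the preset correlation. Such a failure alone therefore does not show that correlation accounts for a call. Other splits of the 6 libraries also called 2 to 14 lists at the preset correlation. Each of them holds both transfections in each group and so keeps a part of the real difference. These splits therefore cannot show whether such list calls arise without the knockdown. Of 21 tested luminal genes 10 fell and 0 rose (15 and 1 adjusted over the list alone, 16 and 1 with the replicate block), with camera adjusted p = 6.05e-08 (adjusted p = 0.629 with an estimated correlation). The keratin KRT7 fell by 1.35 and the transcription factor TFAP2C by 0.53 on the log2 scale. KRT8 fell from 8397 ± 482 to 4838 ± 950 CPM and its partner KRT18 from 4411 ± 71.6 to 2680 ± 410 CPM; these genes overlap, and both have pseudogene copies that may share reads. ESR1, the oestrogen receptor itself, named here after its values were seen, was at 160 ± 23.7 and 125 ± 20.8 CPM and did not pass (limma-voom adjusted p = 0.184; 0.000293 with the replicate block). In the basal and mesenchymal list 2 of 15 tested genes fell and 0 rose (6 and 1 adjusted over the list alone, 8 and 3 with the replicate block), and the list passed no test (camera, adjusted p = 0.0611), although it did without siNT replicate 2 (0.0337) or sip300 replicate 1 (0.0388). These were CD44, a hyaluronan receptor, and KRT17, which fell by 1.17 and 1.89 on the log2 scale; the limma-voom adjusted p of KRT17 was highest, at 0.0653, without siNT replicate 1.

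The type I interferon response genes that passed the test rose. Of 40 tested members 8 rose and 0 fell (18 and 0 adjusted over the list alone, 36 and 1 with the replicate block), and the median member was 0.67 higher on the log2 scale. Without both libraries numbered 2, 4 rose and 0 fell. RSAD2 rose from 3.15 ± 1.85 to 12.4 ± 2.33 CPM (log2 fold change 2.13 ± 0.32 SE, limma-voom adjusted p = 0.00822) and CMPK2 from 8.50 ± 5.26 to 29.4 ± 8.85 CPM. IFIT5 rose from 31.8 ± 8.95 to 60.8 ± 7.54 CPM and the ISG15 protease USP18 from 35.1 ± 9.10 to 58.4 ± 7.36 CPM. Over the fits that leave out 1 library, the limma-voom adjusted p of CMPK2, IFIT5 and USP18 was highest without siNT replicate 1, at 0.0778, 0.0755 and 0.132. At the preset correlation the list was higher than other genes (camera, adjusted p = 7.86e-10), but it did not pass with an estimated correlation (camera, adjusted p = 0.629). Taken pair by pair, the median log2 fold change of the list was 0.76, 0.84 and 0.38 in replicates 1, 2 and 3.

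**Figure D2:**
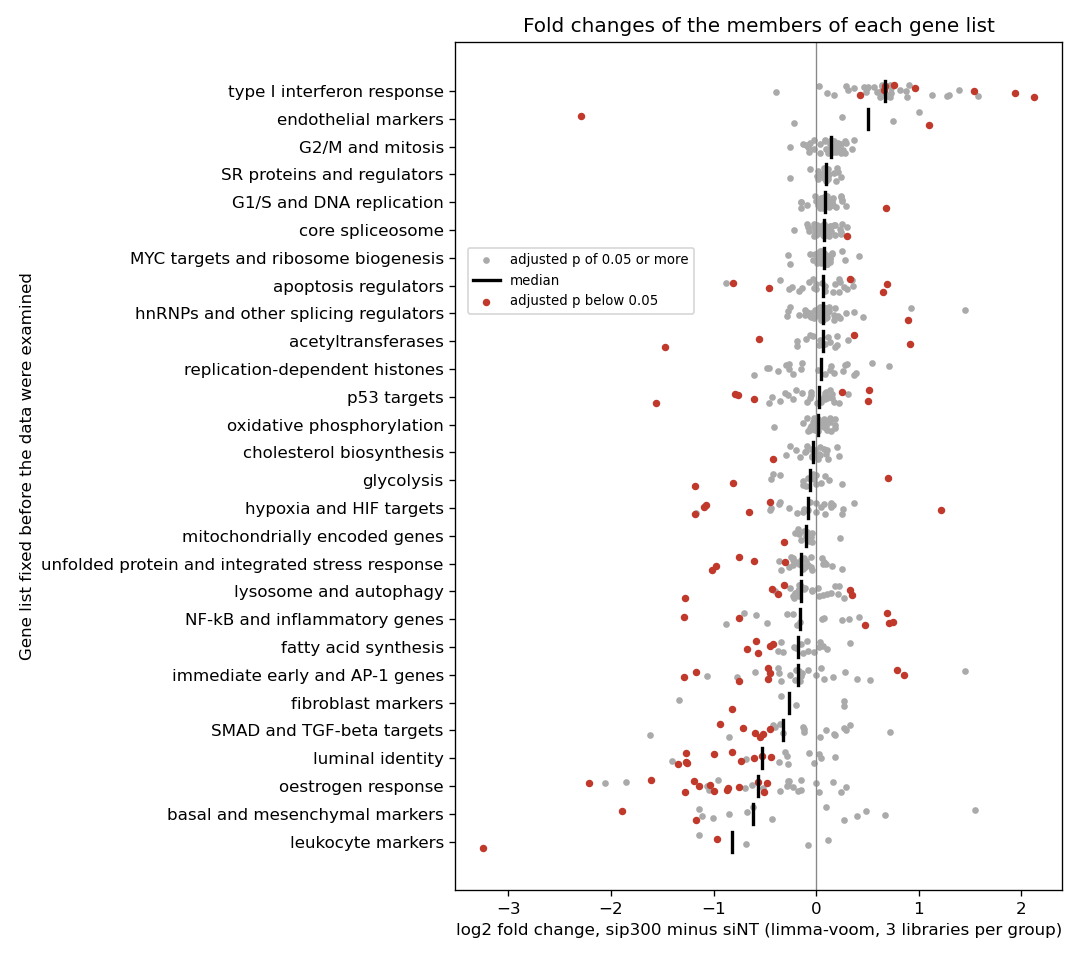
Log2 fold change (sip300 minus siNT, limma-voom, 3 libraries per group) of every tested member of the 28 gene lists, with red points for genes past the adjusted p threshold and a black bar at the list median. The oestrogen-response, luminal and type I interferon lists have medians of -0.57, -0.53 and 0.67.

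In the G1/S and DNA replication list 1 of 38 tested genes rose and 0 fell (1 and 0 adjusted over the list alone, 10 and 1 with the replicate block). The gene was CCNE1, which encodes cyclin E1 (30.5 ± 1.94 to 48.9 ± 3.95 CPM, limma-voom adjusted p = 0.00546). The list median was 0.09 (camera, adjusted p = 0.0249; adjusted p = 0.772 with an estimated correlation), and the call ended without siNT replicate 1 (0.382), siNT replicate 3 (0.0774), sip300 replicate 2 (0.432) or sip300 replicate 3 (0.0502). In the G2/M list 0 of 37 genes passed alone (0 adjusted over the list alone, 18 higher and 1 lower with the replicate block) and the median was 0.15 (camera, adjusted p = 0.00761; adjusted p = 0.714 with an estimated correlation), with no call without siNT replicate 1 (0.0699) or sip300 replicate 3 (0.0502). PRC1 and CCNB1, which have roles in cytokinesis and entry into mitosis, had log2 fold changes of 0.28 and 0.24 (limma-voom adjusted p = 0.0743 and 0.0794; 0.00107 and 0.00371 with the replicate block). Of 22 SR proteins and their regulators 0 passed (0 adjusted over the list alone, 5 higher and 1 lower with the replicate block), the median being 0.09 (camera, adjusted p = 0.0170; adjusted p = 0.675 with an estimated correlation, 0.0706 without siNT replicate 1 and 0.117 without sip300 replicate 3). Of 43 core spliceosome genes SNRPD1 rose, from 81.6 ± 2.74 to 100.4 ± 4.66 CPM, and 0 fell (0 and 0 adjusted over the list alone, 10 and 1 with the replicate block); its limma-voom adjusted p was 0.0386 and became 0.20 without siNT replicate 1. That list had a median of 0.08 (camera, adjusted p = 0.0249; adjusted p = 0.726 with an estimated correlation), with values of 0.133, 0.176 and 0.160 without siNT replicate 1, siNT replicate 3 and sip300 replicate 2. Of 44 hnRNPs and other splicing regulators KHDRBS3 rose, from 1.07 ± 0.329 to 1.93 ± 0.216 CPM (limma-voom adjusted p = 0.0497; 0.137 without sip300 replicate 2), and 0 fell (0 and 0 adjusted over the list alone, 10 and 4 with the replicate block). The list itself had camera adjusted p = 0.0895 (0.0445 with the replicate block, 0.0388 without sip300 replicate 1 and 0.0293 without sip300 replicate 2). It had adjusted p = 0.696 with an estimated correlation and 0.685 with the block as well. Of 32 MYC targets and ribosome biogenesis genes 0 passed (0 adjusted over the list alone, 4 higher and 2 lower with the replicate block, camera, adjusted p = 0.188, and 0.000338 without siNT replicate 2). MYC had a log2 fold change of -0.28 (limma-voom adjusted p = 0.0919; 0.00856 with the replicate block).

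In the SMAD and TGF-beta list 6 of 23 tested genes fell and 0 rose (9 and 1 adjusted over the list alone, 12 and 5 with the replicate block), among them the decoy receptor BAMBI (250 ± 5.77 to 171 ± 13.7 CPM). Its camera adjusted p was 0.0170 (adjusted p = 0.629 with an estimated correlation, 0.0547 without siNT replicate 1). In the immediate early list 6 of 30 genes fell and 2 rose (8 and 4 adjusted over the list alone, 14 and 6 with the replicate block), with camera adjusted p = 0.0202 (adjusted p = 0.629 with an estimated correlation, 0.0753 without siNT replicate 1 and 0.0845 without sip300 replicate 3). The phosphatases of MAP kinases DUSP4 and DUSP5 fell by 0.76 and 1.17 on the log2 scale. In the unfolded protein and integrated stress response list 5 of 30 genes fell and 0 rose (6 and 0 adjusted over the list alone, 13 and 0 with the replicate block), with camera adjusted p = 0.00218 (adjusted p = 0.675 with an estimated correlation, 0.137 without siNT replicate 2). HERPUD1, a component of degradation at the endoplasmic reticulum, fell from 53.2 ± 6.82 to 26.1 ± 0.999 CPM and the transcription factor CEBPB from 49.7 ± 3.87 to 32.7 ± 2.97 CPM. Of 34 p53 targets 3 rose and 4 fell (3 and 4 adjusted over the list alone, 6 and 10 with the replicate block), and the list passed no test (camera, adjusted p = 0.658). Its median of 0.02 was positive while its mean of -0.09 and its test were negative. GDF15, a secreted stress cytokine, fell from 68.7 ± 5.74 to 23.5 ± 3.62 CPM and PLK2 by 0.79 on the log2 scale. Among 19 NF-kB and inflammatory genes 4 rose and 2 fell (5 and 3 adjusted over the list alone, 7 and 6 with the replicate block), NFKB1 rising 1.39-fold (camera, adjusted p = 0.880). The median of -0.16 and mean of -0.09 were negative and the test positive. Of 29 hypoxia and HIF targets 1 rose and 5 fell (2 and 6 adjusted over the list alone, 4 and 10 with the replicate block), the glucose transporter SLC2A1 falling from 170 ± 18.4 to 75.2 ± 7.18 CPM and NDRG1 by 1.08 on the log2 scale (camera, adjusted p = 0.136). Of 28 apoptosis regulators 3 rose and 2 fell (4 and 2 adjusted over the list alone, 10 and 6 with the replicate block, camera, adjusted p = 0.298). Of the 18 acetyltransferases 2 rose and 2 fell (3 and 2 adjusted over the list alone, 6 and 4 with the replicate block, camera, adjusted p = 0.575), and EP300 itself and the nuclear receptor co-activator NCOA3 (log2 fold change -0.56, limma-voom adjusted p = 0.00636) were the falls.

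In the fatty acid synthesis list 5 of 20 genes fell and 0 rose (9 and 1 adjusted over the list alone, 11 and 1 with the replicate block), with camera adjusted p = 0.00173 (adjusted p = 0.629 with an estimated correlation). GPAM, which starts glycerolipid synthesis, fell from 32.7 ± 1.61 to 22.1 ± 1.20 CPM, and FASN, the fatty acid synthase, from 2867 ± 274 to 2144 ± 74.5 CPM, the latter with limma-voom adjusted p = 0.0190, or 0.0772 without sip300 replicate 1. Of 32 lysosome and autophagy genes 4 fell and 2 rose (4 and 2 adjusted over the list alone, 16 and 5 with the replicate block), CTSD among the falls. That list had camera adjusted p = 0.0460 (adjusted p = 0.696 with an estimated correlation), and 0.297, 0.0548 and 0.220 without siNT replicate 2, sip300 replicate 1 and sip300 replicate 3. Of 24 cholesterol biosynthesis genes 1 fell, FDFT1, and 0 rose (1 and 0 adjusted over the list alone, 4 and 2 with the replicate block, camera, adjusted p = 0.406). FDFT1 had limma-voom adjusted p = 0.0164, and 0.0826 without sip300 replicate 1. Of 18 glycolytic genes 1 rose and 2 fell (2 and 4 adjusted over the list alone, 2 and 5 with the replicate block, camera, adjusted p = 0.245), the neuronal enolase ENO2 rising 1.62-fold and SLC2A1 being one of the falls. None of 33 nuclear-encoded oxidative phosphorylation genes passed (limma-voom, 0 adjusted over the list alone, 4 higher and 0 lower with the replicate block, camera, adjusted p = 0.406).

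In the mitochondrially encoded list MT-CO1 fell 1.24-fold and 0 of 13 genes rose (2 lower and 1 higher adjusted over the list alone, 4 and 1 with the replicate block), beside the lower mitochondrial share of counts in sip300. MT-CO1 had limma-voom adjusted p = 0.0130 (0.0727 without sip300 replicate 1), and the list camera adjusted p = 0.0300 (adjusted p = 0.629 with an estimated correlation, 0.0952 without siNT replicate 2 and 0.0677 without sip300 replicate 2). Replication-dependent histones, which lack poly(A) tails, passed in 0 of 22 genes (0 adjusted over the list alone, 4 higher and 2 lower with the replicate block, camera, adjusted p = 0.658). Of 6 tested leukocyte markers 2 fell and 0 rose (2 and 0 adjusted over the list alone, 3 and 0 with the replicate block, camera, adjusted p = 0.0202; adjusted p = 0.629 with an estimated correlation, and 0.0896 with no filter beyond a total above 0). CSF1R, the receptor of a macrophage growth factor, fell from 3.21 ± 0.663 to 0.373 ± 0.198 CPM and the actin-bundling LCP1 by 0.97 on the log2 scale; the limma-voom adjusted p of LCP1 was highest, at 0.102, without sip300 replicate 1. Of 6 fibroblast markers COL6A3 fell and 0 rose (1 and 0 adjusted over the list alone, 2 and 0 with the replicate block, camera, adjusted p = 0.166). Of 6 endothelial markers ESAM rose and VWF fell (2 higher and 1 lower adjusted over the list alone, 3 and 1 with the replicate block, camera, adjusted p = 0.245). The limma-voom adjusted p reached 0.0849 for COL6A3 and 0.0950 for ESAM without siNT replicate 1, and 0.118 for VWF without sip300 replicate 1. Among the list members named here, KRT7 overlaps KRT86 and the pseudogene KRT87P, ESR1 overlaps SYNE1, NCOA3 overlaps SULF2, ENO2 overlaps LRRC23, CSF1R overlaps the pseudogene RPL7P1, CEBPB, SLC2A1 and PRC1 overlap antisense genes, and CTSD, HERPUD1, FDFT1 and ESAM overlap genes known only by clone names, so their reads are uncertain to that extent.

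Alternative splicing differed between the groups in all 5 event types of the authors' deposited rMATS tables. An event was counted as changed where the authors' adjusted p was below 0.05 and the inclusion level, a fraction between 0 and 1, differed by at least 0.1. Skipped exons changed in 2307 of 79348 events (1751 genes), retained introns in 296 of 7676 (279 genes), alternative 3' splice sites in 596 of 26592 (542 genes), alternative 5' splice sites in 597 of 20191 (544 genes) and mutually exclusive exons in 574 of 13989 (439 genes). The tables also hold a pair of yes or no significance columns by the authors, whose rule is not given in the sources used here. The first (JnR_Sig) marks 729 of the changed skipped exons, 119 retained introns, 112 and 108 alternative 3' and 5' sites and 213 mutually exclusive exons, in 956 genes altogether, and both columns mark 521, 73, 88, 84 and 90. Differences are coded as first minus second rMATS group, and the sources used here do not give which transfection was first, so no direction of inclusion is stated. Of all changed skipped exons 1283 had the negative and 1024 the positive sign. Among them, 477 of the 729 marked ones (65.4%) had the negative sign and 252 the positive one, while the marked retained introns divided into 54 negative and 65 positive.

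**Figure D3:**
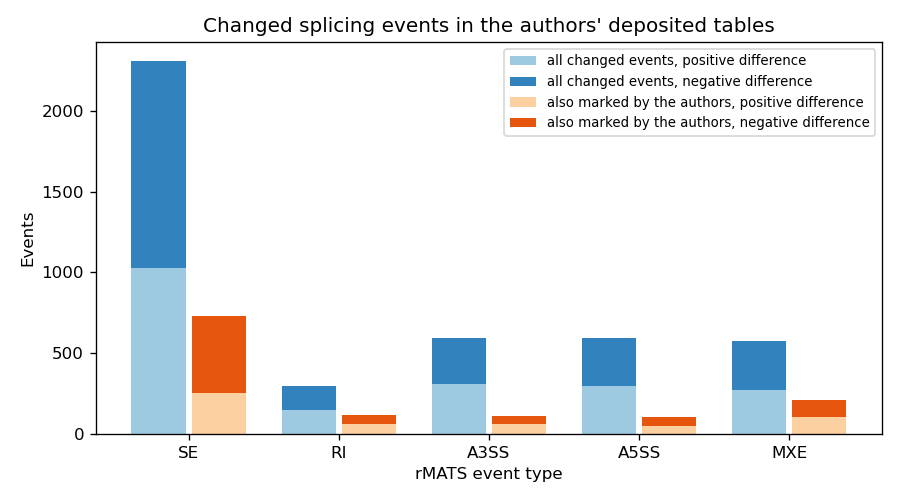
Number of changed events per rMATS type (SE skipped exon, RI retained intron, A3SS and A5SS alternative 3' and 5' splice site, MXE mutually exclusive exons) in the authors' deposited tables, stacked by the sign of the inclusion difference. Blue bars are all changed events and orange bars those that the authors' first significance column also marks; of the marked skipped exons 477 have the negative and 252 the positive sign.

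Named events were taken from the marked ones, with 1-based GRCh38 coordinates and values from the authors' deposited tables. The largest positive skipped-exon differences lay in TMEM45A (0.483; chromosome 3, 100570609 to 100574659, a non-coding annotated exon), RPS3 (0.333; chromosome 11, 75401640 to 75401656, coding sequence with no annotated exon of these bounds), the collagen chaperone SERPINH1 (0.327; chromosome 11, 75563727 to 75563770, an untranslated exon), the readthrough locus ATP6V1G2-DDX39B (0.324) and NDE1 (0.277; chromosome 16, 15699729 to 15699854, a coding exon of 126 bp). The largest negative ones lay in FRG1HP (-0.496; chromosome 9, 40993253 to 40993434), the non-coding RP11-434D9.1 (-0.432), C5orf63 (-0.355; chromosome 5, 127056397 to 127056506), TXNDC17 (-0.354; chromosome 17, 6640976 to 6641100) and ATP5J (-0.346; chromosome 21, 25734989 to 25735030). TXNDC17 and ATP5J likewise have no annotated exon of these bounds. FRG1HP and RPS3 belong to families with near-identical copies, so their events are uncertain. Among retained introns MMS22L had the largest positive difference (0.919; chromosome 6, 97263335 to 97268002), followed by IKBKB (0.404) and COPS6 (0.398), and DDX26B (-0.676), COL7A1 (-0.513) and the ribosomal gene RPL3 (-0.451) the largest negative ones. Alternative 3' sites differed most in CERS5 (0.451), ZNF721 (0.369), CCDC74A (0.330), SMTN (-0.507), MFSD10 (-0.311) and SORBS3 (-0.272), and alternative 5' sites in ZMYM5 (0.377), PCBP1-AS1 (0.322), DUS3L (0.267), ADGRF4 (-0.249), NDUFV3 (-0.247) and SLC25A19 (-0.238). Mutually exclusive exons differed most in XPO1 (0.363), KIAA1468 (0.292), KYNU (0.259), CCDC113 (-0.400), RDM1 (-0.296) and PTPN18 (-0.262). Their adjusted p-values in the deposited tables ranged from 2.43e-144 for FRG1HP to 0.0470 for IKBKB. The authors' second significance column does not mark the events of TMEM45A, IKBKB, DDX26B, COL7A1, CERS5 and MFSD10. Nor does it mark those of SORBS3, ZMYM5, NDUFV3, XPO1 and KYNU. Mean expression was only 3.32 CPM for TMEM45A and 2.75 CPM for RDM1.

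CD44, a gene whose variant exons are a textbook case of regulated splicing, held 32 events in the authors' deposited tables, of which 3 changed. All 3 were skipped coding exons on chromosome 11 with lengths that are multiples of 3 and a negative sign. The event of the exon at 35196746 to 35196874 differed by -0.134 (authors' adjusted p = 8.82e-18). For 1 event of the exon at 35198121 to 35198246 the difference was -0.210 (0.0132). For 1 event of the exon at 35211246 to 35211449 it was -0.160 (5.96e-07). With other flanking exons, the exon at 35198121 to 35198246 had differences of -0.011, 0.024 and 0.079. The exon at 35211246 to 35211449 had differences of -0.066 and 0.024 (authors' adjusted p = 1 for each of these 5 events). The first significance column marks the 3 changed events, and of these both columns mark only the one at 35211246 to 35211449. The event with a difference of 0.079 is marked by the second column alone. The other 29 events in those tables had differences between -0.290 and 0.116 and a lowest adjusted p of 0.0754. The gene as a whole fell from 43.7 ± 8.90 to 19.3 ± 2.33 CPM (log2 fold change -1.17 ± 0.16 SE, limma-voom adjusted p = 0.00559).

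**Figure D4:**
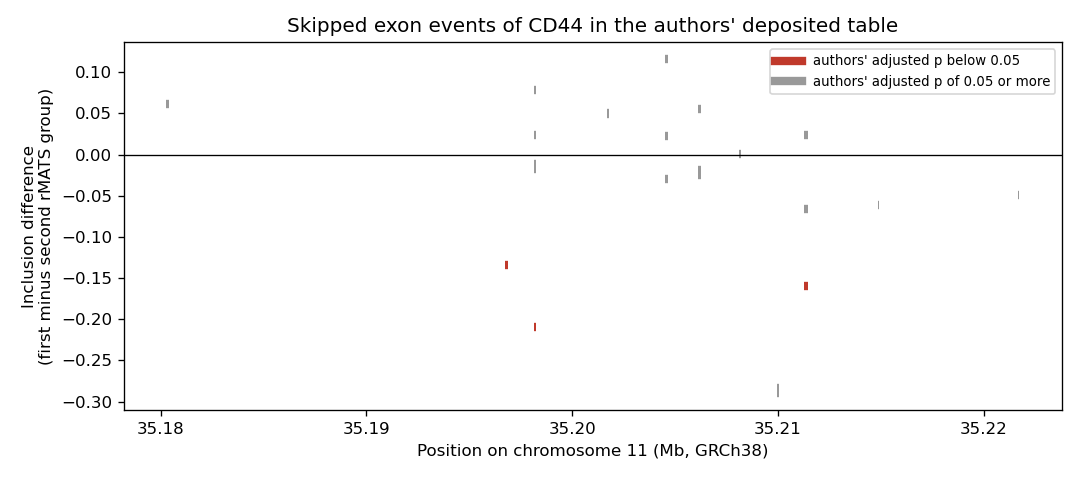
Inclusion difference (first minus second rMATS group) of the 23 CD44 skipped-exon events in the authors' deposited table against the position of the exon on GRCh38 chromosome 11 in Mb, each bar spanning 1 exon. The 3 red events have an adjusted p below 0.05 and differences of -0.134, -0.210 and -0.160.

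Transcripts of splicing factors themselves were among the changed events. By the authors' deposited tables, 104 of 110 members of the 3 splicing lists held an event and 25 held a changed one, 29 events in all. The first significance column marks 11 of these, in 10 genes. Over all genes 2987 held a changed event and 956 a marked one, and skipped-exon events alone lay in 11478 genes. Whether splicing factors changed more often than other genes was not tested. All 11 marked events had the negative sign. They were a coding exon of MBNL1 (-0.176; chromosome 3, 152446704 to 152446757), an overlapping 48 bp form of it (-0.203) and coding sequence of MBNL2 (-0.110; chromosome 13, 97366501 to 97366553), the last 2 with no annotated exon of these bounds, skipped exons of CELF1 (-0.164), HNRNPDL (-0.105) and TRA2A (-0.100), retained introns of CLK1 (-0.117), RBM25 (-0.102) and HNRNPH3 (-0.100), an alternative 5' site of SNRPE (-0.152) and mutually exclusive exons of SFPQ (-0.107). None of these 10 genes passed the expression test (limma-voom; the lowest adjusted p was 0.0950, for TRA2A). With the replicate block TRA2A, HNRNPDL and MBNL1 passed (limma-voom adjusted p = 0.00836, 0.000961 and 0.00311). The 18 events without that mark divided into 10 negative and 8 positive ones. Their median size was 0.5, with values as large as -1 in HNRNPA2B1 and PRPF4 and 1 in SNRPD3. No minimum of coverage could be applied to them, so few reads may lie behind such values. Among them the second column marks the events of ESRP2 (-0.165), RBM39 (-0.132) and SNRNP70 (0.117).

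The overlap of genes with a changed skipped exon and genes changed in expression did not pass. Of 11141 genes tested for both, 1691 held a changed exon and 1075 changed in expression, and 175 were in both sets (10.3% of genes with and 9.52% of genes without a changed exon; odds ratio 1.10, 95% confidence interval 0.919 to 1.30, two-sided Fisher's exact test p = 0.284, adjusted p = 0.354 over 10 tests). The odds ratio was 0.801, 1.26 and 1.38 within the lower, middle and upper tertile of mean expression (Fisher's exact test p = 0.117, 0.143 and 0.0653, none past the threshold). For marked events, chosen after the data were seen, it was 1.19 over all genes (Fisher's exact test p = 0.210) and 0.585, 1.21 and 1.85 within the lower, middle and upper tertile (Fisher's exact test p = 0.175, 0.365 and 0.00705). The last had a 95% confidence interval of 1.16 to 2.85 and did not pass after adjustment (adjusted p = 0.0705). With the replicate block the odds ratio was 0.977 for all changed events (Fisher's exact test p = 0.685), and for marked ones its interval was 0.941 to 1.34 (p = 0.196).

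Changed skipped exons were slightly shorter than unchanged ones. Over 2234 changed and 59682 unchanged exons the median lengths were 108.5 and 116 bp, a difference of -7.5 bp (two-sided permutation test, p = 2e-05, adjusted p = 2.8e-05 over 7 tests). By sign, the 1006 exons with a positive difference differed by -10 bp in the median (106 and 116 bp, permutation test, adjusted p = 2.33e-05), while the 1245 with a negative one did not pass (112 and 116 bp, permutation test, adjusted p = 0.0753). The direction turned over among the 704 marked exons, whose median of 131 bp lay 15 bp above that of unchanged exons (permutation test, p = 1e-05, the smallest it can give, adjusted p = 2.33e-05). Lengths that are multiples of 3 made up 38.7% of changed and 39.1% of unchanged exons (odds ratio 0.983, 95% confidence interval 0.900 to 1.07, Fisher's exact test p = 0.707).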

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

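Chosen after the results were seen were the fits without both libraries numbered 2 and with a pseudocount of 1, the use of the authors' significance columns, and the blocked forms of the overlap, of the estimated list correlation and of the sign of skipped exons. EP300 kept its fall in all 16 alternatives (log2 fold change -1.60 to -1.33, limma-voom adjusted p 9.91e-07 to 0.0169). The 16 genes named by size kept their sign in all 256 combinations of gene and setting and passed in 235. They had been chosen for large changes without overlap of the groups, so the kept sign largely follows from that choice. CREBBP, which passed no test, ranged from -0.00706 to 0.0896 on the log2 scale when 1 library was left out, the lowest without siNT replicate 2, with -0.00420 without sip300 replicate 1, and the cause was not tested.

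The number of called genes was 1684 and rose to 6238 with the replicate block and 6306 with the block and GC content and length offsets. It fell to 626 with a minimum of 2-fold, which by construction keeps fewer genes, and lay between 518 and 1872 with 1 library left out. The other scalings, filters and pseudocounts gave 1502 to 1933 genes, and 2196 passed without both libraries numbered 2. Of the 28 lists 14 passed at the preset correlation, 8 to 15 with 1 library left out, 11 with GC content and length offsets, 12 with the block and these offsets, and 0 with the correlation estimated, with or without the replicate block (0). Without the block every called list had an estimate above the preset 0.01. With the block the SMAD list (estimate -0.0259) still went from camera adjusted p = 0.00399 to 0.685. The blocked leukocyte list (-0.115) went from 0.0224 to 0.685. Failure of all lists with an estimated correlation therefore cannot show that correlation between members accounts for the calls. The oestrogen, luminal, interferon and fatty acid lists passed in every setting at the preset correlation. The block changed no list call other than that of the hnRNPs. The leukocyte list lost its call with no filter beyond a total above 0 (camera adjusted p = 0.0896). The SR list lost it with GC content and length offsets (0.0731) and with the block and offsets (0.0668), and the lysosome list with library totals (0.0528) and the offsets (0.05003). The mitochondrially encoded list lost it with library totals (0.0528), pseudocounts of 0.1 (0.0626) and 1 (0.124), the offsets (0.0505), the block and offsets (0.0671) and without both libraries numbered 2 (0.0729). Calls were gained by the basal list with library totals (0.0215), no filter (0.0208) and at least 1 CPM (0.0499), by the MYC list with totals (0.0463), no filter (0.0380) and without both libraries numbered 2 (0.00184), by the hnRNP list under the same settings (0.0160, 0.00899 and 0.0321), and by the fibroblast list with at least 1 CPM (0.0329). The cause was not tested.

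A minimum difference of 0.2 left 1317 skipped exons, 180 retained introns and 270 mutually exclusive exons. The first significance column left 729, 119, 112, 108 and 213 skipped exons, retained introns, alternative 3' sites, alternative 5' sites and mutually exclusive exons, and both columns left 521, 73, 88, 84 and 90. The overlap odds ratio of 1.10 turned to 0.801 in the lower tertile of expression, 0.585 for marked events there and 0.977 with the replicate block, and was 1.85 for marked events in the upper tertile (Fisher's exact test p = 0.00705, adjusted p = 0.0705 over 10 tests). Among marked exons the odds ratio of lengths that are multiples of 3 was 1.10 and the length difference 15 bp, and the cause of these turns was not tested. No paired analysis was possible because the splicing and CD44 columns could not be tied to libraries, and for the same reason leaving out libraries, count minimums of 10 and 50 and a test on logit inclusion were not run. The planned count models were not run either. The floor of 3 counts, or 0.0376 to 0.0518 CPM, was set here and is no measured limit of detection. The tests had a higher limit, at least 10 counts in a library of median size in at least 3 libraries.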

Other observations

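The gene families and single genes named here, the counts of other splits, the share of negative signs with the replicate block and the test of a different siRNA were chosen after the results were seen. CYP26A1, a retinoic acid hydroxylase (chromosome 10, 93073475 to 93077890), rose from 0.217 ± 0.115 to 3.17 ± 0.766 CPM (log2 fold change 3.98 ± 0.43 SE, limma-voom adjusted p = 0.00272). The CYP family as a whole did not pass, with 5 of 26 genes higher (Fisher's exact test, adjusted p = 0.234).

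Of 241 families named by symbol and 482 Fisher's exact tests, 4 passed, 3 of them for families with more lower genes than others and 1 for a family with fewer. Keratins were lower in 9 of 22 tested genes against 6.37% of others (adjusted p = 0.00100, 19 with the replicate block, 9 under both other scalings), with KRT81 falling from 1715 ± 280 to 591 ± 142 CPM and KRT86 from 23.0 ± 0.511 to 6.21 ± 2.90 CPM, a near-identical pair whose reads may be shared, so each value is uncertain. Calpains were lower in 6 of 11 (adjusted p = 0.00389, 6 with the replicate block, 6 and 5 under median-of-ratios factors and library totals), CAPN2 falling from 50.2 ± 6.11 to 21.3 ± 3.06 CPM. Aldehyde dehydrogenases were lower in 6 of 16 (adjusted p = 0.0382, 8 with the replicate block, 6 and 5 under those scalings), ALDH3B2 falling from 79.7 ± 20.8 to 14.8 ± 1.50 CPM. The percentages of others are from the fit without the block. With the block 3016 of all 19166 tested genes were lower, so blocked counts are not to be set against those percentages. Zinc finger genes of the ZNF family were less often lower than others, in 6 of 454 against 6.60% (adjusted p = 7.42e-05, 31 with the replicate block, 7 and 4 under those scalings). They were higher in 9 of 454 against 4.48% of others, which did not pass (Fisher's exact test p = 0.00716, adjusted p = 0.242). The keratin result is not independent of the luminal list, which shares members with it.

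The type I interferon list was higher in sip300 at the preset correlation (camera, adjusted p = 7.86e-10). It did not pass with an estimated correlation (camera, adjusted p = 0.629, and 0.685 with the replicate block as well). GC content and length bias is argued against, since with the replicate block and offsets for both the median of the 40 members was 0.65 (0.67 before). A single replicate pair is argued against too, as the lowest of the 3 medians taken pair by pair was 0.38. A response to the transfected siRNA itself may account for the rise and cannot be told apart from loss of EP300, because there was only 1 transfection label other than siNT. The loss of EP300 stays open as the biological explanation, untested.

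Skipped exons that changed but were not marked by the authors' first significance column lay in genes of lower median expression than marked ones. The median was 14.2 CPM in 1136 genes holding only such events and 40.8 CPM in 555 genes with marked ones, a difference of -26.5 CPM (permutation test, p = 1e-05, the smallest it can give). In the lower, middle and upper tertile of mean expression 735, 529 and 427 genes held a changed skipped exon, and 115, 251 and 189 a marked one. Genes with unmarked events thus lay in every tertile. Low expression may therefore account for these events in part only. Of these genes 51 and 9 were not tested for expression and were left out, and no biological explanation was tested.

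Marked skipped exons had the negative sign in 64.7% of the 493 genes not called in expression without the replicate block (319 genes, exact 95% interval 60.3 to 68.9%), against 361 of all 564 genes. In the 323 genes not called with the block the share was 63.2% (204 genes, exact 95% interval 57.6 to 68.4%). Of all changed skipped exons, marked or not, 1283 had the negative and 1024 the positive sign. Both shares argue against a change in expression of the host genes as the whole cause. Which transfection came first in the subtraction is not given, so no direction of inclusion follows, and no biological explanation was tested.

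The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. Each split other than the real one holds both transfections in each group. It keeps a part of the real difference and adds to the spread within groups, which can lower the number of genes called. The real split called 1684 genes by limma-voom and the highest of the others 0, so 1 of 10 splits gave as many. With the replicate block it called 6238 and the other 3 splits that part all 3 pairs called 0, while the remaining 6 splits part 1 pair. For gene lists 2 of 10 splits gave as many as the real one, 14 for the real split and 14 for the highest other. The lowest other split called 2 lists. Calls at the preset correlation were thus not limited to the real split, but the mixed splits cannot show whether they arise without the knockdown.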
